A study of Mus musculus with 24 samples.

How the data were processed

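RNA sequencing of GMPs sorted from Ldlr-/- mice gave 24 libraries in 6 groups of diet (CD, WD or WDtoCD) and injection (PBS or 10 µg ultrapure E. coli LPS per mouse, 6 h before sacrifice). CD_PBS held 6 libraries, WD_PBS 4, WDtoCD_PBS 3, CD_LPS 4, WD_LPS 3 and WDtoCD_LPS 4, and CD_PBS 1 and 2 formed batch 1. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these libraries. Libraries were made with the TruSeq RNA Library Prep Kit v2. The submitters' notes name HISAT2 2.0.6, Partek 6.6, R 3.0.2, DESeq2 and the mm10 assembly. The read counter and gene annotation are not given in the sources used here.

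The authors deposited values as signal, read here as gene counts divided by 1 size factor per library, with values under 1 set to the floor of 1. The table holds 11294 genes with a mean of at least 10 in some group. Values above the floor were, within 0.05, whole multiples of a step of 0.282 to 5.48 in each library, which gave 0.674 to 12.5 M recovered reads per library (median 3.77 M) and 63 to 519 genes at the floor. Between replicates the chi-square per degree of freedom was at least 2.89, so spread exceeded that of counting. A gene label in the table was split over 2 lines, and the 2798 labels after it stood 1 line below their values. This was checked by the correlation of each list gene with the rest of its list, which had a median of 0.697 with labels moved by 1 line and 0.0046 as deposited for 69 genes after the split, and 0.795 as deposited for 379 genes before it. Moved labels were used, and the deposited label is given where it differs.

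Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes) for 10572 genes with a mean of at least 10 over all libraries, and 722 were left out. The log2 changes lie on this scale, which understates changes of low genes. The fit held 6 groups and batch as a covariate, with 17 residual degrees of freedom and a prior of 9.30. Batch changed 166 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Values after ± are the standard error for log2 changes and the SD over batch 2 libraries for means. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. Coordinates are those of GRCm38, and 10877 symbols matched 1 GENCODE gene.

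Gene lists, comparisons and the rule for named genes were fixed before the data were examined. Of 26 lists, 1 was the panel of single genes, 2 had under 5 measured members, and 23 were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. They held 705 genes, of which 623 were in the table, 2 under an older symbol. The lists covered inflammation, lipid and energy metabolism, ribosomes, cell cycle, stress, GMP lineages and other cell types. Members were counted by calls over all genes and by calls adjusted over the list alone. Named genes were the 6 largest rises and 6 largest falls among called genes whose batch 2 libraries did not overlap, up to 3 called members per list, and a panel of single genes. The text gives part of these, and its list examples for the LPS responses were taken from those no single library ended. Alternatives were scaling, filter, pseudocount, batch, choice of groups, robust variance and leaving out each library, and after the data were seen also labels as deposited, shallow libraries, library weights, and covariates for Y-linked and immediate early genes. Recovery was tested on simulated data with genes changed by 2-fold and 4-fold.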

Results

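Granulocyte-monocyte progenitors (GMPs) sorted from Ldlr-/- mice kept a measurable Ldlr signal in all 6 groups. Ldlr encodes the receptor that clears low-density lipoprotein from plasma. Its deposited signal was 380.2 ± 24.3 on CD after PBS, 309 ± 88.9 on WD, 403 ± 62.0 on WDtoCD, 620.0 ± 60.1 on CD after LPS, 377 ± 103 on WD after LPS and 667 ± 60.0 on WDtoCD after LPS (mean ± SD, n = 4, 4, 3, 4, 3 and 4 libraries of batch 2). The granule protease gene Elane and the peroxidase gene Mpo were among the strongest signals, with Mpo at 56318 ± 2218 and Elane at 13272 ± 1187 on CD after PBS. Kit stood at 958 ± 123 and Cd34 at 1293 ± 233. CD and WD are the diet names of the labels, and WDtoCD is written for the label WD>CD, read as mice moved from WD to CD. LPS or PBS was injected 6 h before sacrifice.

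Sex-linked transcripts differed between libraries of the same group. Xist (deposited label Xiap), the RNA that silences an X chromosome in cells with more than 1, lay at 9.20 in CD_PBS 4, where the Y-linked helicase gene Ddx3y stood at 379, and at 5072 in CD_PBS 5, where Ddx3y stood at 2.20. Ddx3y exceeded Xist in 2 libraries of each group: CD_PBS 3 and 4, WD_PBS 1 and 2, WDtoCD_PBS 1 and 2, CD_LPS 1 and 2, WD_LPS 1 and 2, and WDtoCD_LPS 1 and 2. WD_LPS 3 held both, with Xist at 8790.0 and Ddx3y at 65.7, where Ddx3y was at most 2.20 in the other libraries with Xist above it. The labels give no sex, and WD_LPS 3 is also the shallowest library, at 0.674 M recovered reads. WDtoCD_PBS 1 held 0.692 M. The first principal component carried 41.1 percent of the variance and separated every library after LPS from every library after PBS.

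**Figure D1:**
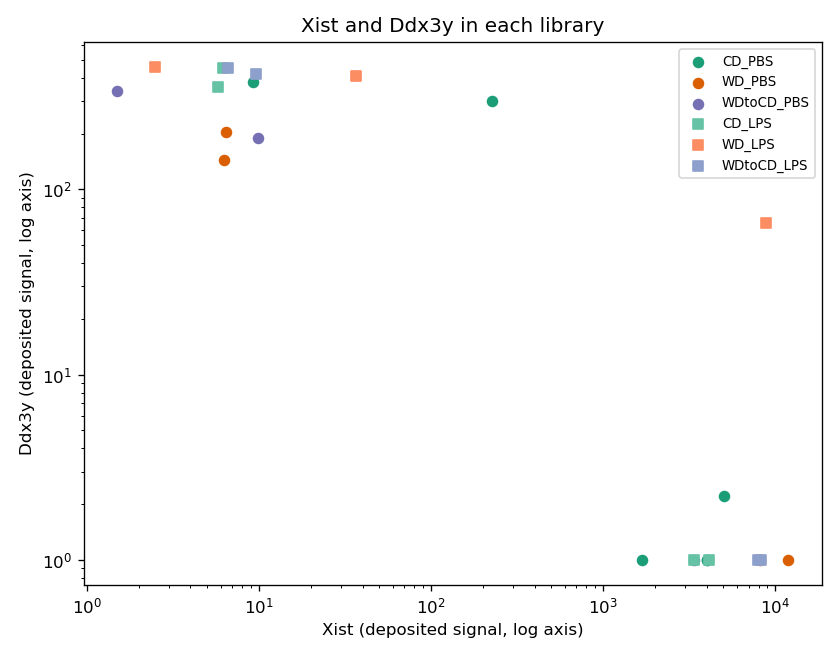
Xist against Ddx3y in each of the 24 libraries, both as deposited signal on log axes. Circles are PBS groups and squares are LPS groups.

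LPS on CD raised Saa3, Ccl5, Cxcl10 and most interferon-stimulated genes. Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase apolipoprotein gene, rose from 18.5 ± 30.1 to 3445 ± 671 (log2 change 8.72 ± 0.65, adjusted p = 2.11e-10, n = 4 and 4). The chemokine genes Ccl5 (7.62 ± 0.59, adjusted p = 2.69e-10) and Cxcl10 (6.82 ± 0.66, adjusted p = 1.89e-08) rose with the interferon-inducible GTPase genes Iigp1 7.33 ± 0.65 and Tgtp1 (deposited label Tgs1) 7.04 ± 0.79. Cfb, a complement factor gene, rose by 6.75 ± 0.54, and Irg1 (now Acod1), which makes itaconate, by 6.69 ± 0.55 (adjusted p = 7.89e-10). CD_PBS 3 held traces of these genes, with Saa3 at 63.5, Ccl5 at 92.9 and Irg1 at 24.7 where no other CD library after PBS exceeded 5.81, 5.81 and 2.04. The largest falls were in Cracr2b (-3.92 ± 0.53), a regulator of calcium entry, the adaptor gene Apba1 (-3.40 ± 0.40), the lectin gene Siglecg (deposited label Siglecf) (-3.24 ± 0.61), the exocytosis gene Stxbp6 (deposited label Stxbp5) (-3.03 ± 0.67), the cytokine receptor gene Il31ra (-2.85 ± 0.50) and the semaphorin receptor gene Nrp1 (-2.85 ± 0.45).

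Of 43 interferon-stimulated genes 42 rose, 0 fell and 1 did not pass (mean 3.26, adjusted p = 1.02e-61, and adjusted p = 3.99e-04 with an estimated correlation), among them the transcription factor gene Irf7 (5.80 ± 0.47), the antiviral synthetase gene Oas3 (5.33 ± 0.56) and the ubiquitin-like gene Isg15 (5.33 ± 0.42). Among 29 interferon-gamma and guanylate-binding protein genes 25 rose, 0 fell and 4 did not pass, and among 30 NF-kB and inflammatory cytokine genes 24 rose, 0 fell and 6 did not pass (means 3.14 and 2.71, adjusted p = 2.26e-46 and 2.78e-31). Both calls held with an estimated correlation (adjusted p = 3.99e-05 for each). The signalling genes Stat1 (deposited label Stard8) (2.19 ± 0.18), Stat3 (deposited label Stat2) (0.81 ± 0.13) and Socs3 (deposited label Socs1) (4.62 ± 0.56), the LPS co-receptor gene Cd14 (3.44 ± 0.42), the interleukin-1 receptor gene Il1r1 (1.85 ± 0.37) and the common beta-chain gene Csf2rb (1.72 ± 0.12, adjusted p = 3.81e-11) rose too. The oxidase subunit gene Cybb (from 587 ± 143 to 3979 ± 609.8, 2.78 ± 0.18) and the siderophore-binding gene Lcn2 (3.14 ± 0.39) were members of the later neutrophil granule list that rose, and the list as a whole was not called (mean -0.28, adjusted p = 0.730).

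Primary granule genes fell on CD after LPS: of 15 members 0 rose, 12 fell and 3 did not pass (mean -1.04, adjusted p = 1.56e-11, adjusted p = 0.140 with an estimated correlation), with the serine protease gene Prss57 (-1.81 ± 0.34), the lectin gene Clec12a (-1.64 ± 0.17), Elane (-1.13 ± 0.24) and Mpo (-0.82 ± 0.17, from 56318 ± 2218 to 32108 ± 4816) among them. Of 19 monocyte lineage genes 0 rose, 6 fell and 13 did not pass (mean -0.45, adjusted p = 8.56e-04, adjusted p = 0.333 with an estimated correlation), among them the transglutaminase gene F13a1 (-1.77 ± 0.30) and Tifab (deposited label Tifa) (-1.75 ± 0.15), and the lineage factor gene Irf8 fell by 0.98 ± 0.16. Ribosome biogenesis and MYC target genes moved up: 23 rose, 0 fell and 12 did not pass among 35 (mean 0.46, adjusted p = 4.23e-14, adjusted p = 0.0982 with an estimated correlation), with Noc4l (0.87 ± 0.17), Mybbp1a (0.79 ± 0.11) and Myc itself (0.77 ± 0.13, adjusted p = 1.65e-04). Of 24 cholesterol biosynthesis genes 7 rose, 0 fell and 17 did not pass (mean 0.30, adjusted p = 0.00404, adjusted p = 0.333 with an estimated correlation), including Hsd17b7 (1.25 ± 0.27) and Cyp51 (0.96 ± 0.19), beside Hmgcr (0.48 ± 0.11) and Ldlr (0.70 ± 0.18). Of 24 unfolded protein response genes 3 rose, 10 fell and 11 did not pass (mean -0.25, adjusted p = 3.53e-05, adjusted p = 0.333 with an estimated correlation), with the disulfide isomerase gene Pdia4 at -1.06 ± 0.20. Of 17 eosinophil, basophil and mast cell genes 7 rose, 0 fell and 10 did not pass (mean 1.39, adjusted p = 9.45e-05, adjusted p = 0.333 with an estimated correlation), and the eosinophil granule gene Prg2 rose by 2.24 ± 0.49.

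On CD, LPS left 856 genes higher and 543 lower among 10572 tested. The remaining called lists were megakaryocyte and erythroid (mean 0.77, adjusted p = 4.18e-04, and 0.333 with an estimated correlation). Stem and multipotent progenitor genes were called too (mean 0.87, adjusted p = 0.00238, and 0.341 with an estimated correlation). Fatty acid oxidation genes were called too (mean -0.18, adjusted p = 0.0320, and 0.333 with an estimated correlation). Oxidative phosphorylation genes were called too (mean -0.19, adjusted p = 3.36e-04, and 0.566 with an estimated correlation). Only fatty acid oxidation was lost when a library was left out, and that library was CD_PBS 4 (adjusted p = 0.0626). The monocyte lineage mean was -0.23 without CD_LPS 1 and -0.68 without CD_LPS 2, and the megakaryocyte and erythroid mean 0.51 without CD_PBS 4. Receptors and regulators that did not pass were given as values: Nlrp3 1.55 ± 0.64 (adjusted p = 0.120), the LPS receptor gene Tlr4 (deposited label Tlr3) 0.02 ± 0.29 (adjusted p = 0.982), and the colony-stimulating factor receptor genes Csf1r 0.30 ± 0.16, Csf2ra -0.48 ± 0.19 and Csf3r -0.48 ± 0.22. The lineage factor genes Cebpa 0.01 ± 0.18, Cebpb 0.81 ± 0.28, Cebpd -0.54 ± 0.31 and Spi1 (deposited label Sphk2) 0.23 ± 0.14 and the chromatin genes Dnmt3a -0.10 ± 0.17, Tet2 (deposited label Tet1) 0.03 ± 0.28 and Setd4 (deposited label Setd3) 0.42 ± 0.51 did not pass. The same held for Kit 0.08 ± 0.16, Cd34 -0.30 ± 0.14, Flt3 0.35 ± 0.33, Il1rap 0.19 ± 0.22, Hk2 0.39 ± 0.13 and Ly6c2 -0.46 ± 0.27. Of the 1399 called genes, 808 stayed called without each single library.

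LPS on WD raised Cxcl10, Gbp6 and most interferon-stimulated genes. Cxcl10 (chromosome 5, 92346638 to 92348889) rose from 3.55 ± 3.44 to 5971 ± 1255 (log2 change 10.63 ± 0.72, adjusted p = 1.33e-11, n = 4 and 3). The guanylate-binding protein gene Gbp6 rose by 8.96 ± 0.48 (adjusted p = 3.37e-13), with Iigp1 9.44 ± 0.70, Tgtp1 9.07 ± 0.85, Ccl5 9.65 ± 0.63 and Saa3 9.60 ± 0.71. Irg1 was listed at the floor of 1 in all 4 WD libraries after PBS and at 1010.0 ± 588 after LPS. The largest falls were in Apba1 (-3.78 ± 0.44, adjusted p = 2.56e-07), the monocyte factor gene Klf4 (-3.68 ± 0.62), Tmem119 (deposited label Tmem115) (-3.67 ± 0.42), the liprin gene Ppfia4 (-3.59 ± 0.51), and the DNA repair genes Rdm1 (-3.60 ± 0.58) and Ddb2 (-3.26 ± 0.61).

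Of 43 interferon-stimulated genes 42 rose, 0 fell and 1 did not pass on WD (mean 4.09, adjusted p = 2.29e-56, adjusted p = 6.59e-04 with an estimated correlation), with the antiviral gene Ifit1 (7.78 ± 0.55), Irf7 (6.73 ± 0.51) and the nucleic acid sensor gene Zbp1 (deposited label Zbed6) (6.49 ± 0.54). Of 29 interferon-gamma and guanylate-binding protein genes 27 rose, 0 fell and 2 did not pass. Of 30 NF-kB and inflammatory cytokine genes 27 rose, 0 fell and 3 did not pass (means 4.22 and 3.36, adjusted p = 5.20e-05 for each with an estimated correlation). The receptor genes Tlr2 (deposited label Tlr13) (2.41 ± 0.27) and Cd14 (2.67 ± 0.45), the inflammatory caspase gene Casp4 (2.32 ± 0.34), the stem cell antigen gene Ly6a (5.31 ± 0.46), Stat1 (3.02 ± 0.19), Csf2rb (2.14 ± 0.13) and Cybb (from 304 ± 19.6 to 3387 ± 300.3, 3.47 ± 0.19) rose. Nlrp3, whose product assembles an inflammasome, did not pass (1.64 ± 0.70, adjusted p = 0.0915). Of 15 later neutrophil granule genes 3 rose, 0 fell and 12 did not pass (mean 1.27, adjusted p = 0.00361, adjusted p = 0.434 with an estimated correlation), with Lcn2 3.37 ± 0.42 and Ngp 2.82 ± 0.71. Of 17 eosinophil, basophil and mast cell genes 10 rose, 0 fell and 7 did not pass (mean 1.87, adjusted p = 1.83e-06, adjusted p = 0.252 with an estimated correlation), with Prg2 3.58 ± 0.53 and Epx 3.23 ± 0.73.

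Of 15 primary granule genes 0 rose, 10 fell and 5 did not pass (mean -1.10, adjusted p = 3.82e-08, adjusted p = 0.252 with an estimated correlation), with Prss57 -2.06 ± 0.37, Cebpe -1.68 ± 0.41 and Clec12a -1.42 ± 0.19 besides Elane (-1.39 ± 0.26) and Mpo (-1.15 ± 0.19). Of 20 fatty acid oxidation genes 1 rose, 10 fell and 9 did not pass (mean -0.36, adjusted p = 0.00420, adjusted p = 0.252 with an estimated correlation), Acaa2 at -0.98 ± 0.20 and Acadl in the other direction at 1.30 ± 0.20. Of 52 oxidative phosphorylation genes 0 rose, 8 fell and 44 did not pass (mean -0.33, adjusted p = 2.69e-05, adjusted p = 0.504 with an estimated correlation), Cox7a2 at -0.88 ± 0.22. Of 34 G2/M cell cycle genes 0 rose, 6 fell and 28 did not pass (mean -0.36, adjusted p = 0.00209, adjusted p = 0.478 with an estimated correlation), including the mitotic kinase gene Plk1 (-1.39 ± 0.27) and Kif2c (-1.06 ± 0.26), and this call was lost without WD_LPS 3 (adjusted p = 0.0514). The mevalonate kinase gene Mvk fell by 1.84 ± 0.40 while Hmgcr rose by 0.57 ± 0.12, and cholesterol biosynthesis genes as a list were not called (mean -0.12, adjusted p = 0.692). Irf8 (-1.02 ± 0.18), Cebpa (-0.74 ± 0.19) and Cd34 (-0.63 ± 0.15) fell.

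In all, LPS on WD left 1216 genes higher and 1176 lower. Further called lists were megakaryocyte and erythroid, and ribosome biogenesis and MYC target genes (means 1.04 and 0.31, adjusted p = 0.359 for each with an estimated correlation). Tissue macrophage genes were called too (mean 1.18, adjusted p = 0.253 with an estimated correlation). Stem and multipotent progenitor genes were called too (mean 0.90, adjusted p = 0.478 with an estimated correlation). Unfolded protein response genes were called too (mean -0.10, adjusted p = 0.576 with an estimated correlation). Their mean was 0.0805 without WD_LPS 3. Monocyte lineage genes were called too (mean -0.30, adjusted p = 0.478 with an estimated correlation). Leaving out WD_LPS 3 ended the calls of the last 4 of these (adjusted p = 0.0961, 0.271, 0.393 and 0.153), WD_PBS 3 also ended that of unfolded protein response genes, and WD_PBS 2, WD_PBS 3 or WD_LPS 1 also ended that of monocyte lineage genes. The oxidative phosphorylation mean was -0.19 without WD_PBS 2. Calls of 1248 of the 2392 genes held without each single library. Another division of the 7 libraries, with WD_PBS 1, 2 and 3 as a group, gave 1755 genes, and the median of the others was 2.5.

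After the return to CD, LPS raised Cxcl10, Tgtp1 and most interferon-stimulated genes. Cxcl10 rose from 2.47 ± 2.17 to 1443 ± 413 (log2 change 8.83 ± 0.72, adjusted p = 7.56e-10, n = 3 and 4), and Tgtp1 8.43 ± 0.85, Iigp1 8.34 ± 0.70, Ccl5 8.25 ± 0.63, Gbp6 7.85 ± 0.48 and Saa3 7.44 ± 0.71 rose. Irg1 stood at the floor of 1 in all 3 WDtoCD libraries after PBS and at 319 ± 68.3 after LPS. The largest falls were in Nrp1 (-4.00 ± 0.48, adjusted p = 8.54e-07), the claudin gene Cldn15 (-3.76 ± 0.47), Ppfia4 (-3.40 ± 0.51), the heat shock gene Hspa1b (-3.23 ± 0.92), the neutrophil adaptor gene Pram1 (-3.23 ± 0.50) and Apba1 (-3.22 ± 0.44). Nlrp3 passed on WDtoCD, from 6.69 ± 5.35 to 43.3 ± 17.5 (2.81 ± 0.70, adjusted p = 0.00722), and lost its call without WDtoCD_PBS 1 (adjusted p = 0.1). The difference of its response from that on CD did not pass (1.26 ± 0.95, adjusted p = 0.998).

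Of 43 interferon-stimulated genes 42 rose, 0 fell and 1 did not pass on WDtoCD (mean 3.87, adjusted p = 1.14e-69, adjusted p = 1.99e-04 with an estimated correlation), with Zbp1 7.05 ± 0.54, Ifi204 7.04 ± 0.60, Isg15 6.81 ± 0.45 and Irf7 5.61 ± 0.51. Of 29 interferon-gamma and guanylate-binding protein genes 25 rose, 0 fell and 4 did not pass. Of 30 NF-kB and inflammatory cytokine genes 23 rose, 0 fell and 7 did not pass (means 3.53 and 2.74, adjusted p = 4.03e-05 and 8.27e-05 with an estimated correlation). Stat1 2.71 ± 0.19, Cd14 2.38 ± 0.45, Il18rap 2.79 ± 0.34, Csf2rb 2.21 ± 0.13, Cybb 3.63 ± 0.19, Lcn2 3.74 ± 0.42 and Ly6a 4.12 ± 0.46 rose. Of 24 cholesterol biosynthesis genes 11 rose, 0 fell and 13 did not pass (mean 0.73, adjusted p = 1.75e-08, adjusted p = 0.0634 with an estimated correlation), with the demethylase gene Cyp51 (1.61 ± 0.21), Hsd17b7 (1.43 ± 0.30) and the rate-limiting reductase gene Hmgcr (0.91 ± 0.12). Of 10 LXR target and cholesterol efflux genes 0 rose, 4 fell and 6 did not pass (mean -0.68, adjusted p = 0.0139, adjusted p = 0.223 with an estimated correlation), including the transporter gene Abcg1 (-2.82 ± 0.56), and that list was lost without WDtoCD_PBS 3 (adjusted p = 0.0515).

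Primary granule genes fell on WDtoCD after LPS: of 15 members 0 rose, 12 fell and 3 did not pass (mean -1.26, adjusted p = 5.89e-13, adjusted p = 0.101 with an estimated correlation): Prss57 -2.61 ± 0.37, Mgst1 -1.90 ± 0.34, Elane -1.70 ± 0.26 and Mpo -1.29 ± 0.19. Of 19 monocyte lineage genes 1 rose, 7 fell and 11 did not pass (mean -0.40, adjusted p = 0.00244, adjusted p = 0.305 with an estimated correlation), with F13a1 -2.51 ± 0.32, Ly6c2 -1.46 ± 0.30 and Klf4 -2.60 ± 0.62, and Irf8 fell by 1.03 ± 0.18. Of 17 eosinophil, basophil and mast cell genes 9 rose, 0 fell and 8 did not pass (mean 1.70, adjusted p = 5.75e-06, adjusted p = 0.223 with an estimated correlation), with Ear1 at 4.01 ± 0.87. Ribosome biogenesis and MYC target genes were called as well (mean 0.34, adjusted p = 0.223 with an estimated correlation). Unfolded protein response genes were called as well (mean -0.21, adjusted p = 0.386 with an estimated correlation). Fatty acid oxidation and oxidative phosphorylation genes were called as well (means -0.22 and -0.28, adjusted p = 0.272 and 0.486 with an estimated correlation). Without WDtoCD_PBS 3 the oxidative phosphorylation and unfolded protein response means were -0.17 and -0.11. G2/M (mean -0.18, adjusted p = 0.662 with an estimated correlation) and G1/S genes (mean -0.13, adjusted p = 0.374 with an estimated correlation) were called, the former lost without WDtoCD_PBS 2, WDtoCD_LPS 3 or WDtoCD_LPS 4 (adjusted p up to 0.128) and the latter without WDtoCD_PBS 3 or WDtoCD_LPS 2 (up to 0.170).

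The WDtoCD response to LPS comprised 743 genes higher and 544 lower. It fell from 1287 to 740 genes without the shallow library WDtoCD_PBS 1. Calls were lost by 2 named genes without WDtoCD_PBS 1 (adjusted p = 0.0567 to 0.1), 1 without WDtoCD_LPS 1 (0.0626), 1 without WDtoCD_LPS 3 (0.0746) and 1 without WDtoCD_PBS 3 (0.0768), and 575 of the 1287 kept their calls without each single library. Another division of the 7 libraries, placing WDtoCD_LPS 4 with the PBS libraries, gave 545 genes.

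**Figure D2:**
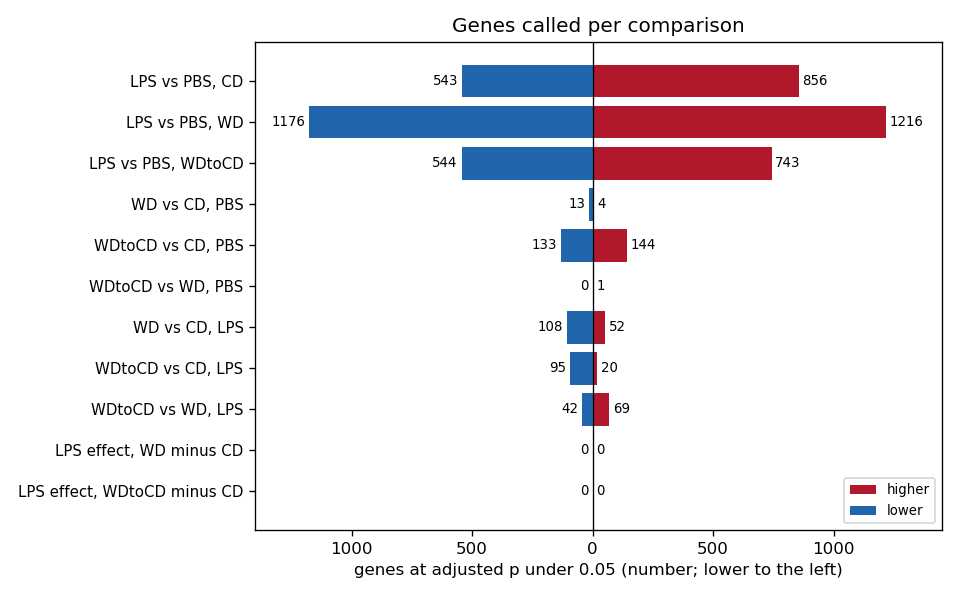
Number of genes with an adjusted p under 0.05 in each of the 11 comparisons, higher to the right and lower to the left.

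The LPS responses of the 3 diets overlapped in 452 genes higher and 250 lower in all of them, where independent calls would share 6.92 and 3.11. The principal axis of log2 changes over genes called in either diet had slope 1.41 for WD against CD (r = 0.892, 2844 genes). For WDtoCD against CD it was 1.12 (r = 0.926, 1881 genes). Unlike a regression slope, it also rises with noise in WD or WDtoCD, so alone it shows no larger response. Over the 702 shared genes the median size was 1.18 on CD, 1.40 on WD and 1.19 on WDtoCD.

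Without LPS, WD lowered a few granule genes in GMPs, and no list held with an estimated correlation. Prg2 (chromosome 2, 84980461 to 84983632), the eosinophil major basic protein gene, fell from 1162 ± 919 to 95.5 ± 31.5 (log2 change -3.38 ± 0.49, adjusted p = 0.00110, n = 4 and 4), and the eosinophil peroxidase gene Epx by 3.23 ± 0.68 (adjusted p = 0.0430). Syne1 (deposited label Syncrip), which ties the nucleus to the cytoskeleton, fell by 1.98 ± 0.28 (adjusted p = 0.00110), the iron exporter gene Slc40a1 (deposited label Slc3a2) by 1.93 ± 0.33, the calcium-binding alarmin gene S100a9 by 2.76 ± 0.59, the leukotriene receptor gene Ltb4r1 by 1.44 ± 0.30 and Cybb by 0.92 ± 0.18. Higher were the early progenitor receptor gene Flt3 (1.71 ± 0.33, adjusted p = 0.0239), the mitochondrial gene Chchd6 (1.15 ± 0.24), the antiviral gene Ifitm3 (0.88 ± 0.16) and the tRNA methylase gene Trmt1 (deposited label Trit1) (0.87 ± 0.17). Mpo (-0.07 ± 0.17), Elane (-0.47 ± 0.24), Fcnb (-3.11 ± 0.70, adjusted p = 0.0565), Cd34 (0.61 ± 0.14), Nlrp3 (-0.41 ± 0.64) and Hmgcr (-0.42 ± 0.11, adjusted p = 0.140) did not pass.

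Of 17 eosinophil, basophil and mast cell genes 0 rose, 2 fell and 15 did not pass. Over the list alone 0 were higher and 12 lower (mean -1.84, adjusted p = 2.17e-14, adjusted p = 0.0538 with an estimated correlation). Of 15 later neutrophil granule genes 0 rose, 3 fell and 12 did not pass. Adjusted within the list, 0 were higher and 9 lower (mean -1.48, adjusted p = 1.70e-12, adjusted p = 0.0538 with an estimated correlation). Cholesterol biosynthesis genes had 0 called members over all genes and 0 higher and 9 lower adjusted over the list alone (mean -0.45, adjusted p = 1.13e-09, adjusted p = 0.0538 with an estimated correlation), and stem and multipotent progenitor genes 2 higher and 0 lower (mean 0.40, adjusted p = 8.80e-04, adjusted p = 0.473 with an estimated correlation). Megakaryocyte and erythroid genes were called (mean 0.52, adjusted p = 2.01e-04, and 0.473 with an estimated correlation). Immediate early and dissociation stress genes were called (mean 1.17, adjusted p = 6.07e-07, and 0.283 with an estimated correlation). Primary granule genes were called (mean -0.52, adjusted p = 7.79e-05, and 0.474 with an estimated correlation). Ribosome biogenesis and MYC target genes were called (mean 0.14, adjusted p = 2.85e-04, and 0.521 with an estimated correlation). The immediate early mean was 0.70 without WD_PBS 1 and 0.86 without WD_PBS 2. Oxidative phosphorylation and ribosomal protein genes were called (means 0.15 and 0.14, both adjusted p = 0.688 with an estimated correlation) and lost without WD_PBS 1 or WD_PBS 2 (adjusted p up to 0.915 and 0.907). TLR and inflammasome components (mean -0.20, adjusted p = 0.0244, adjusted p = 0.373 with an estimated correlation) were lost without WD_PBS 2 or WD_PBS 3 (up to 0.139), and G2/M genes (mean 0.17, adjusted p = 0.00301, adjusted p = 0.564 with an estimated correlation) without CD_PBS 3 (0.137). CD_PBS 4 scored 1.05 and 1.26 on the eosinophil and later neutrophil granule lists, and CD_PBS 3, 5 and 6 scored -0.781 to -0.0960 and -0.654 to -0.0786. Without CD_PBS 4 the means of megakaryocyte and erythroid, stem and multipotent progenitor, and ribosome biogenesis genes were 0.26, 0.22 and 0.0816.

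WD against CD after PBS gave 4 genes higher and 13 lower, beside 1165 genes at an unadjusted p under 0.05 where 528.6 are expected by chance. Syne1 and Prg2 kept their calls without each single library. The other 9 did not. Calls were lost by 9 named genes without CD_PBS 4 (adjusted p = 0.0925 to 0.254), 9 without WD_PBS 2 (0.0512 to 0.119) and 7 without CD_PBS 6 (0.0507 to 0.108). There were 5 without CD_PBS 3 (0.0796 to 0.125), 5 without WD_PBS 1 (0.0630 to 0.139) and 4 without CD_PBS 5 (0.0522 to 0.0738). There were 2 without WD_PBS 3 (0.0604 to 0.0737) and 2 without WD_PBS 4 (0.0700 to 0.0731). The count itself became 2 without WD_PBS 2, 3 without CD_PBS 4, 6 without CD_PBS 6, 11 without CD_PBS 3, 11 without CD_PBS 5, 11 without WD_PBS 1 and 26 without WD_PBS 3, and 2 with a covariate for immediate early genes. In simulated values, with noise independent between genes and alike in all libraries, the test recovered 66 of 100 genes changed 2-fold and 96 of 100 changed 4-fold. Recovery in these data may be lower.

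Mice returned to CD differed from CD mice in 277 genes after PBS. The erythropoietin receptor gene Epor (chromosome 9, 21958897 to 21963506) rose from 2.11 ± 1.07 to 38.9 ± 4.47 (log2 change 3.74 ± 0.76, adjusted p = 0.00671, n = 4 and 3). The carbonic anhydrase gene Car1 rose by 3.62 ± 0.74 (adjusted p = 0.00671), Flt3 by 2.08 ± 0.35 (adjusted p = 0.00187), Pdgfrb by 1.60 ± 0.32, the lipoprotein gene Apoe by 1.21 ± 0.25 and Cd34 by 0.86 ± 0.15 (adjusted p = 0.00209). The erythroid genes Pklr 3.2 ± 0.77, Ermap 3.09 ± 0.70, Aqp1 3.05 ± 0.67 and Klf1 2.89 ± 0.62 and the thrombopoietin receptor gene Mpl (2.53 ± 0.56) rose as well. The chitinase-like gene Chil3 fell from 489.8 ± 528 to 20.6 ± 13.5 (-4.33 ± 0.70, adjusted p = 0.00160), with the lectin receptor gene Clec4a2 (-4.08 ± 0.64), the alarmin genes S100a8 -3.98 ± 0.60 and S100a9 -3.79 ± 0.64, the ficolin gene Fcnb (-3.84 ± 0.75), the antimicrobial gene Camp (-3.79 ± 0.94) and the adhesion gene Vcam1 (deposited label Vbp1) (-2.35 ± 0.45). The monocyte antigen gene Ly6c2 (-1.36 ± 0.30) and Prg2 (-2.40 ± 0.53) fell.

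Of 15 stem and multipotent progenitor genes 8 rose, 0 fell and 7 did not pass. Over the list alone 10 were higher and 0 lower (mean 1.20, adjusted p = 2.11e-13, adjusted p = 0.0633 with an estimated correlation). Of 25 megakaryocyte and erythroid genes 13 rose, 0 fell and 12 did not pass (mean 1.17, adjusted p = 1.56e-11, adjusted p = 0.105 with an estimated correlation). Of 15 later neutrophil granule genes 0 rose, 8 fell and 7 did not pass (mean -2.0, adjusted p = 2.11e-13, adjusted p = 0.0633 with an estimated correlation). Of 15 primary granule genes 0 rose, 2 fell and 13 did not pass. Adjusted within the list, 0 were higher and 12 lower (mean -0.88, adjusted p = 2.91e-10, adjusted p = 0.183 with an estimated correlation). Of 19 monocyte lineage genes 0 rose, 1 fell and 18 did not pass (mean -0.67, adjusted p = 2.54e-04, adjusted p = 0.262 with an estimated correlation). TLR and inflammasome components were called (mean -0.42, adjusted p = 0.00187, and 0.122 with an estimated correlation). Immediate early and dissociation stress genes were called (mean 1.01, adjusted p = 5.46e-04, and 0.487 with an estimated correlation). Of 17 eosinophil, basophil and mast cell genes 1 rose, 2 fell and 14 did not pass (mean -1.04, adjusted p = 0.0116, adjusted p = 0.610 with an estimated correlation), a call lost without WDtoCD_PBS 2 or CD_PBS 4 (adjusted p up to 0.0934). Unfolded protein response genes (mean -0.22, adjusted p = 0.00146, adjusted p = 0.610 with an estimated correlation) were lost without WDtoCD_PBS 2 (0.153). No list stayed called with an estimated correlation.

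WDtoCD against CD after PBS gave 144 genes higher and 133 lower. Of the called genes named for this comparison, Epor, Car1, Flt3, Pdgfrb, Apoe, Cd34, Chil3, Clec4a2, S100a8, S100a9 and Vcam1 kept their calls without each single library. Calls were lost by 6 named genes without CD_PBS 4 (adjusted p = 0.0561 to 0.148), 4 without WDtoCD_PBS 1 (0.0574 to 0.155) and 4 without WDtoCD_PBS 2 (0.0504 to 0.108). There were 4 without WDtoCD_PBS 3 (0.0524 to 0.0687), 1 without CD_PBS 3 (0.0555) and 1 without CD_PBS 6 (0.0509). The count became 106 without CD_PBS 4, 133 without WDtoCD_PBS 1, 141 without WDtoCD_PBS 2 and 156 without CD_PBS 6, and 172 with the immediate early covariate.

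Between WDtoCD and WD after PBS only Fads2 passed. Fads2 (chromosome 19, 10062765 to 10101746), a fatty acid desaturase gene under sterol control, rose from 27.6 ± 9.44 to 96.1 ± 19.1 (log2 change 1.79 ± 0.29, adjusted p = 0.0120, n = 4 and 3), and its call was lost without WD_PBS 1 (adjusted p = 0.0811), WDtoCD_PBS 2 (0.141) or WDtoCD_PBS 3 (0.101). The sterol regulator gene Srebf2 (deposited label Srebf1) (0.76 ± 0.18, adjusted p = 0.193), the progenitor gene Myct1 (1.90 ± 0.38), Car2 (1.42 ± 0.29), Irf8 (-0.59 ± 0.18), Cybb (-0.82 ± 0.19) and Ly6c2 (-0.87 ± 0.30) did not pass. Stem and multipotent progenitor genes were called higher (mean 0.80, adjusted p = 5.61e-09, and 0.165 with an estimated correlation). Megakaryocyte and erythroid genes were called higher (mean 0.65, adjusted p = 1.29e-07, and 0.248 with an estimated correlation). Eosinophil, basophil and mast cell genes were called higher (mean 0.80, adjusted p = 2.62e-06, and 0.296 with an estimated correlation). Cholesterol biosynthesis genes were called higher (mean 0.36, adjusted p = 1.29e-07, and 0.165 with an estimated correlation). Each had 0 called members over all genes, and in this order 7 higher and 0 lower, 7 higher and 0 lower, 3 higher and 0 lower and 6 higher and 0 lower over the lists alone. Monocyte lineage genes (mean -0.45, adjusted p = 2.07e-05, adjusted p = 0.248 with an estimated correlation) were called lower. These 5 of 13 called lists kept their calls without each single library, and none of the 13 stayed called with an estimated correlation. The cholesterol mean was 0.23 without WDtoCD_PBS 3. Each of the other 8 lost its call without WDtoCD_PBS 2, among them oxidative phosphorylation genes (mean -0.24, adjusted p = 0.473 with an estimated correlation, then 0.0530), and 5 of the 8 lost it without another library too. The count of 1 gene became 0 without WD_PBS 1, 0 without WDtoCD_PBS 3, 2 without WD_PBS 3 and 2 without WD_PBS 4, and 891 genes had an unadjusted p under 0.05. Division of these 7 libraries by chance gave at least 1 gene in 11 of 35, and 1810 with WD_PBS 1, WD_PBS 2 and WDtoCD_PBS 3 as a group.

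The WD and WDtoCD differences from CD after PBS shared 2 genes higher and 10 lower, where independent calls would share 0.0545 and 0.164. Flt3 and Ifitm3 were the shared genes higher. Across genes the log2 changes correlated at 0.629 (covariance 0.127), and unchanged groups sharing the same CD libraries gave a mean correlation of 0.435 in simulation (range -0.423 to 0.767) and a covariance of 0.0503. With the CD libraries split between the comparisons the correlation was 0.390 to 0.511 and the shared genes 0 to 3. The 12 shared genes became 2 without CD_PBS 4, 2 without WD_PBS 2, 5 without CD_PBS 6 and 6 without WD_PBS 1.

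**Figure D3:**
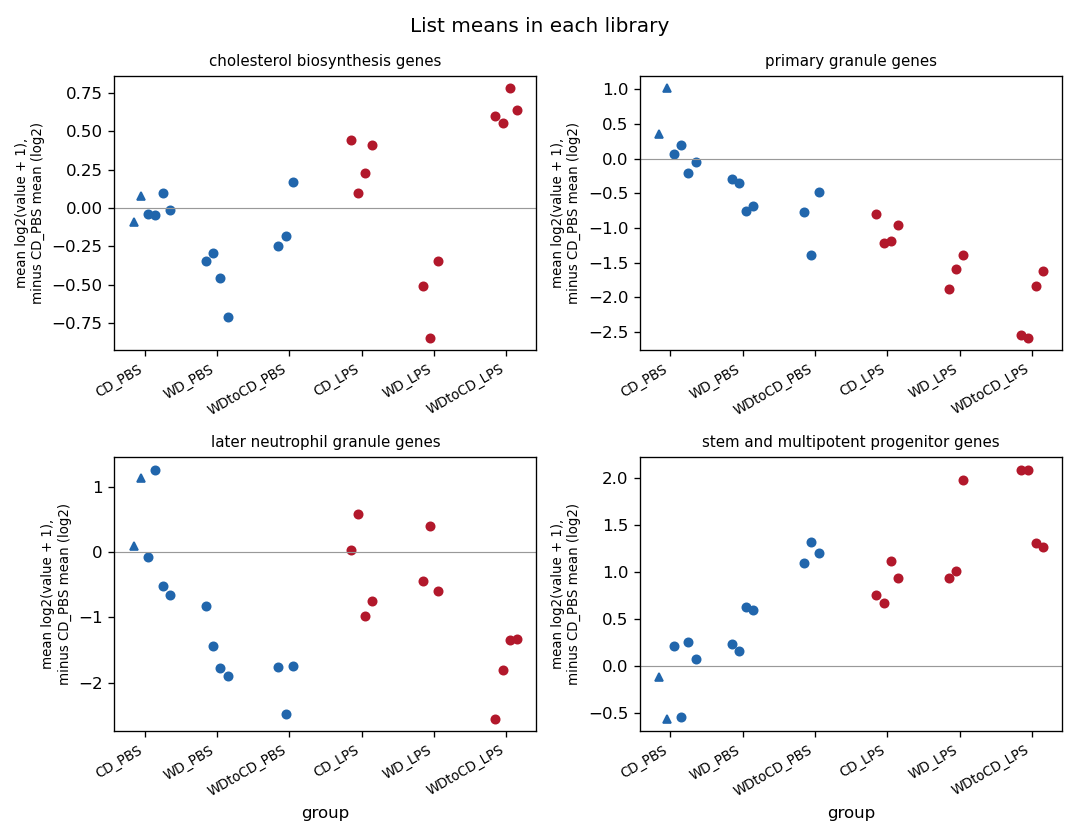
Mean log2(value + 1) of the members of 4 gene lists in each library, minus the mean of the 4 batch 2 CD_PBS libraries. Blue marks PBS, red marks LPS, and triangles mark the 2 batch 1 libraries.

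After LPS, WD mice had lower cholesterol biosynthesis genes and higher interferon-gamma-inducible genes than CD mice. The squalene epoxidase gene Sqle (deposited label Spty2d1) (chromosome 15, 59315077 to 59331192) fell from 244 ± 35.8 to 94.1 ± 63.3 (log2 change -1.58 ± 0.27, adjusted p = 0.00354, n = 4 and 3). The sterol desaturase gene Sc5d fell by 1.52 ± 0.23 (adjusted p = 0.00178), Mvk by 1.92 ± 0.40 and Ldlr by 0.75 ± 0.20 (adjusted p = 0.0491). The cholesterol efflux gene Abca1 rose by 2.73 ± 0.62 (adjusted p = 0.0282). Tmem119 (-3.22 ± 0.42, adjusted p = 3.80e-04), the actin-binding gene Lima1 (-2.80 ± 0.52) and the eosinophil ribonuclease genes Ear1 -3.47 ± 0.87, Ear2 -3.94 ± 1.02 and Ear6 -4.96 ± 1.08 fell, and the serpin gene Serpinb10 (deposited label Serpina3n) was listed at the floor of 1 in all 3 WD libraries and at 17.4 ± 10.6 on CD (adjusted p = 0.0205). Car1 (3.17 ± 0.74), the cytokine gene Lif (2.85 ± 0.63), the checkpoint genes Pdcd1 (2.64 ± 0.60) and Cd274 (1.53 ± 0.29), the chemokine gene Cxcl11 (2.57 ± 0.55), the esterase gene Ces2g (2.46 ± 0.64) and the guanylate-binding protein genes Gbp4 1.87 ± 0.43 and Gbp5 1.37 ± 0.31 rose.

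Of 24 cholesterol biosynthesis genes 0 rose, 10 fell and 14 did not pass. Over the list alone 0 were higher and 18 lower (mean -0.86, adjusted p = 6.54e-19, adjusted p = 0.00418 with an estimated correlation). Of 29 interferon-gamma and guanylate-binding protein genes 4 rose, 0 fell and 25 did not pass. Adjusted within the list, 22 were higher and 0 lower (mean 0.87, adjusted p = 1.45e-19, adjusted p = 0.00418 with an estimated correlation). Of 30 NF-kB and inflammatory cytokine genes 3 rose, 0 fell and 27 did not pass (mean 0.59, adjusted p = 1.45e-07, adjusted p = 0.0427 with an estimated correlation), with the feedback genes Tnfaip3 (deposited label Tnfaip2) (1.37 ± 0.31) and Nfkbia (1.0 ± 0.26). Interferon-stimulated genes were called (mean 0.75, adjusted p = 6.31e-15, and 0.117 with an estimated correlation). Megakaryocyte and erythroid genes were called (mean 0.79, adjusted p = 1.33e-06, and 0.193 with an estimated correlation). Immediate early and dissociation stress genes were called (mean 1.21, adjusted p = 2.04e-05, and 0.224 with an estimated correlation). Primary granule genes were called (mean -0.58, adjusted p = 1.67e-04, and 0.360 with an estimated correlation). The interferon-stimulated mean was 0.50 without WD_LPS 3. WD_LPS 3 also ended the calls of LXR target and cholesterol efflux (mean 0.72, adjusted p = 0.00320, adjusted p = 0.138 with an estimated correlation), tissue macrophage (mean 0.82, adjusted p = 0.00813, adjusted p = 0.185 with an estimated correlation) and dendritic cell and MHC class II genes (mean 0.43, adjusted p = 0.00907, adjusted p = 0.193 with an estimated correlation) when left out (adjusted p = 0.105, 0.167 and 0.185). Leaving out CD_LPS 2 ended that of eosinophil, basophil and mast cell genes (mean -1.36, adjusted p = 6.47e-04, adjusted p = 0.341 with an estimated correlation, then 0.151). Stem and multipotent progenitor, ribosomal protein, glycolysis and G2/M genes were called with the preset correlation alone (means 0.44, 0.0800, -0.18 and -0.19, adjusted p = 0.341 to 0.814 with an estimated correlation), and WD_LPS 3 ended each of these calls when left out (adjusted p = 0.384, 0.188, 0.509 and 0.509).

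WD against CD after LPS gave 52 genes higher and 108 lower. Sc5d, Sqle, Lima1 and Tmem119 kept their calls without each single library. Calls were lost by 17 named genes without CD_LPS 4 (adjusted p = 0.0576 to 0.143), 14 without CD_LPS 2 (0.0541 to 0.151) and 9 without CD_LPS 3 (0.0552 to 0.109). There were 8 without CD_LPS 1 (0.0524 to 0.111), 8 without WD_LPS 1 (0.0554 to 0.167) and 8 without WD_LPS 2 (0.0563 to 0.0877). There were 4 without WD_LPS 3 (0.0506 to 0.118). The count became 21 without CD_LPS 4, 46 without CD_LPS 2, 56 without CD_LPS 3, 81 without CD_LPS 1, 302 without WD_LPS 1 and 364 without WD_LPS 3.

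After LPS, mice returned to CD had lower Ly6c2, Fcnb and Elane than CD mice. Ly6c2 (chromosome 15, 75108158 to 75111970) fell from 4068 ± 105 to 902 ± 506 (log2 change -2.36 ± 0.27, adjusted p = 4.46e-05, n = 4 and 4). Fcnb (-4.33 ± 0.70, adjusted p = 0.00227), Chil3 -3.48 ± 0.65, S100a8 -3.47 ± 0.55, Prom1 -3.35 ± 0.60, Mgl2 -3.04 ± 0.58 and Mcemp1 -2.94 ± 0.54, Elane (-1.48 ± 0.24, adjusted p = 0.00227), the transferase gene Mgst1 (-1.76 ± 0.32), Mpo (-0.76 ± 0.17) and Cd14 (-1.96 ± 0.42) fell. The mucin gene Muc13 rose by 1.06 ± 0.19 (adjusted p = 0.00557), with Mfsd2b 1.69 ± 0.42, Flt3 1.36 ± 0.33, Pdgfrb 1.31 ± 0.29, Sox4 (deposited label Sox13) 1.13 ± 0.25 and Spns2 (deposited label Spns1) 1.03 ± 0.25. Nlrp3 (-0.71 ± 0.64), Stat1 (0.27 ± 0.18) and Irf7 (0.45 ± 0.47) did not pass.

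Of 15 primary granule genes 0 rose, 7 fell and 8 did not pass. Over the list alone 0 were higher and 11 lower (mean -1.11, adjusted p = 2.76e-19, adjusted p = 0.0767 with an estimated correlation). Of 15 later neutrophil granule genes 0 rose, 5 fell and 10 did not pass (mean -1.48, adjusted p = 7.06e-12, adjusted p = 0.0767 with an estimated correlation). Of 19 monocyte lineage genes 0 rose, 3 fell and 16 did not pass (mean -0.63, adjusted p = 1.86e-05, adjusted p = 0.136 with an estimated correlation). Of 31 TLR and inflammasome components 0 rose, 3 fell and 28 did not pass (mean -0.39, adjusted p = 9.12e-04, adjusted p = 0.0996 with an estimated correlation). The monocyte mean was -0.39 without CD_LPS 2. Of 15 stem and multipotent progenitor genes 1 rose, 0 fell and 14 did not pass. Adjusted within the list, 9 were higher and 0 lower (mean 0.82, adjusted p = 1.46e-10, adjusted p = 0.0767 with an estimated correlation). Glycolysis genes had 0 called members over all genes and 0 higher and 10 lower adjusted over the list alone (mean -0.36, adjusted p = 2.63e-09, adjusted p = 0.0996 with an estimated correlation). Cholesterol biosynthesis and interferon-stimulated genes were called higher (means 0.35 and 0.41, adjusted p = 0.0996 and 0.375 with an estimated correlation). The latter scored 4.04 and 3.94 in WDtoCD_LPS 1 and 2, 3.49 and 3.22 in 3 and 4, and 2.97 to 3.53 on CD. Glycolysis and megakaryocyte and erythroid genes also set libraries 1 and 2 apart. Oxidative phosphorylation and G1/S genes were called lower (means -0.17 and -0.16, adjusted p = 0.564 and 0.196 with an estimated correlation). Interferon-gamma and guanylate-binding protein, and unfolded protein response genes (means 0.18 and -0.18, adjusted p = 0.286 and 0.417 with an estimated correlation) were lost without CD_LPS 4 and WDtoCD_LPS 1 in this order (adjusted p = 0.0754 and 0.177). Megakaryocyte and erythroid genes went both ways, 12 higher and 7 lower adjusted over the list alone (mean 0.26, adjusted p = 0.417 with an estimated correlation), and were lost without WDtoCD_LPS 2 (adjusted p = 0.0652). Dendritic cell and MHC class II genes (mean 0.28, adjusted p = 0.196 with an estimated correlation) were lost without CD_LPS 2 (adjusted p = 0.0731).

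WDtoCD against CD after LPS gave 20 genes higher and 95 lower, and no list stayed called with an estimated correlation. Ly6c2, Fcnb, S100a8, Prom1, Mcemp1, Elane, Mgst1 and Muc13 kept their calls without each single library. Calls were lost by 9 named genes without WDtoCD_LPS 1 (adjusted p = 0.0512 to 0.274), 7 without CD_LPS 3 (0.0546 to 0.0801) and 7 without CD_LPS 4 (0.0549 to 0.103). There were 7 without WDtoCD_LPS 2 (0.0875 to 0.299), 6 without CD_LPS 2 (0.0503 to 0.173) and 3 without CD_LPS 1 (0.0763 to 0.0999). The count became 26 without WDtoCD_LPS 1, 32 without WDtoCD_LPS 2, 41 without CD_LPS 4, 60 without CD_LPS 3 and 232 without WDtoCD_LPS 4.

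Between WDtoCD and WD after LPS, cholesterol biosynthesis genes rose and several inflammatory genes fell. The synthase gene Hmgcs1 (chromosome 13, 119690379 to 119708260) rose from 139 ± 44.3 to 483 ± 74.0 (log2 change 1.84 ± 0.21, adjusted p = 1.04e-05, n = 3 and 4), with Sqle (2.05 ± 0.27, adjusted p = 1.17e-04), Mvk (2.58 ± 0.40, adjusted p = 0.00112), Ldlr (0.86 ± 0.20) and Hmgcr (0.53 ± 0.12). Car3 2.67 ± 0.52, Dip2a 2.64 ± 0.51, Ermard 2.55 ± 0.53 and Cxx1c 2.49 ± 0.61 rose too, and Serpinb10, at the floor of 1 in all 3 WD libraries, stood at 18.7 ± 10.8 on WDtoCD (adjusted p = 0.0152). Ly6c2 (-1.55 ± 0.30, adjusted p = 0.00933), the porphyrin synthase gene Alas2 (-3.02 ± 0.72), S100a8 -2.89 ± 0.60, S100a9 -2.88 ± 0.64 and Chil3 -2.78 ± 0.70, Abca1 (-2.67 ± 0.62), the receptor gene Tlr1 (deposited label Tln1) (-2.61 ± 0.57), Gbp5 (-1.48 ± 0.31), Tnfaip2 (deposited label Tnfaip1) (-1.19 ± 0.23) and the adhesion gene Icam1 (-1.07 ± 0.24) fell.

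Of 24 cholesterol biosynthesis genes 17 rose, 0 fell and 7 did not pass. Over the list alone 21 were higher and 0 lower (mean 1.21, adjusted p = 2.29e-33, adjusted p = 3.53e-04 with an estimated correlation). Of 29 interferon-gamma and guanylate-binding protein genes 0 rose, 1 fell and 28 did not pass. Adjusted within the list, 0 were higher and 10 lower (mean -0.69, adjusted p = 4.22e-11, adjusted p = 0.0272 with an estimated correlation). Of 30 NF-kB and inflammatory cytokine genes 0 rose, 2 fell and 28 did not pass and 0 higher and 8 lower (mean -0.69, adjusted p = 5.47e-09, adjusted p = 0.0272 with an estimated correlation). Tissue macrophage and later neutrophil granule genes were called lower (means -1.08 and -1.54, adjusted p = 0.0549 and 0.126 with an estimated correlation). Monocyte lineage genes were called lower (mean -0.54, adjusted p = 0.155 with an estimated correlation). Unfolded protein response and primary granule genes were called lower (means -0.35 and -0.52, adjusted p = 0.319 and 0.332 with an estimated correlation). The unfolded protein response mean was -0.22 without WDtoCD_LPS 1. LXR target and cholesterol efflux genes (mean -0.69, adjusted p = 0.00417, adjusted p = 0.135 with an estimated correlation) and interferon-stimulated genes (mean -0.33, adjusted p = 1.36e-05, adjusted p = 0.332 with an estimated correlation) were lost without WD_LPS 3 (adjusted p = 0.103 and 0.0626). Oxidative phosphorylation genes (mean -0.18, adjusted p = 2.43e-05, adjusted p = 0.466 with an estimated correlation) kept their call, and the other 7 called lists lost theirs without at least 1 library and with an estimated correlation (adjusted p = 0.428 to 0.746 with an estimated correlation), among them immediate early and dissociation stress genes (mean -0.78, adjusted p = 0.428 with an estimated correlation), lost without WD_LPS 2 (adjusted p = 0.205).

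WDtoCD against WD after LPS gave 69 genes higher and 42 lower. Hmgcs1, Sqle, Mvk, Car3, Dip2a and Ly6c2 kept their calls without each single library. Calls were lost by 14 named genes without WDtoCD_LPS 1 (adjusted p = 0.0536 to 0.177), 10 without WD_LPS 2 (0.0531 to 0.189) and 7 without WDtoCD_LPS 2 (0.0569 to 0.128). There were 4 without WD_LPS 3 (0.0508 to 0.0680), 4 without WDtoCD_LPS 3 (0.05 to 0.0898) and 4 without WDtoCD_LPS 4 (0.0545 to 0.0805). There were 3 without WD_LPS 1 (0.0607 to 0.0996). The count became 31 without WDtoCD_LPS 1, 50 without WDtoCD_LPS 2, 324 without WD_LPS 1 and 373 without WD_LPS 3. Another division of the 7 libraries, with WD_LPS 1, WD_LPS 2, WDtoCD_LPS 3 and WDtoCD_LPS 4 as a group, gave 396 genes, more than the diets did, so chance division is not excluded for this count.

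The WD and WDtoCD differences from CD after LPS shared 3 genes higher and 13 lower. Their log2 changes correlated at 0.425 (covariance 0.0874), unchanged groups sharing the CD libraries gave a mean correlation of 0.430 and a covariance of 0.0526 in simulation, and with the CD libraries split the correlation was 0.179 to 0.291 with 0 genes shared. The 16 shared genes became 1 without CD_LPS 4, 4 without CD_LPS 3, 5 without CD_LPS 2, 6 without WDtoCD_LPS 2, 8 without WDtoCD_LPS 1, 9 without CD_LPS 1, 31 without WD_LPS 3 and 33 without WDtoCD_LPS 4.

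No gene passed the limma test for a difference between the LPS responses on WD and CD, though the interferon-gamma-inducible genes as a list were larger on WD. The iron exporter gene Slc40a1 fell on CD (-2.26 ± 0.33) and did not pass on WD, a difference of 2.5 ± 0.49 (adjusted p = 0.105, n = 3, 4, 4 and 4). Further differences that did not pass were those of the interferon-inducible gene Ifit2 (1.76 ± 0.40, adjusted p = 0.138), Gbp6 (2.77 ± 0.65, adjusted p = 0.141), Mvk (-1.93 ± 0.54, adjusted p = 0.230), Nlrp3 (0.09 ± 0.95, adjusted p = 0.986) and Stat1 (0.83 ± 0.26, adjusted p = 0.280). Of 29 interferon-gamma and guanylate-binding protein genes none was called over all genes, and 11 higher and 0 lower adjusted over the list alone (mean 1.08, adjusted p = 1.24e-13, adjusted p = 0.0326 with an estimated correlation). CD_PBS 3 scored 0.664 on this list, above other CD_PBS libraries (at most -0.0489), which enlarged this difference. The other 8 called lists did not hold with an estimated correlation, among them interferon-stimulated, NF-kB and inflammatory cytokine, and cholesterol biosynthesis genes (means 0.83, 0.65 and -0.41, adjusted p = 1.47e-11, 2.25e-05 and 1.90e-04, adjusted p = 0.216, 0.135 and 0.254 with an estimated correlation), whose calls no single library ended. The cholesterol mean was -0.27 without WD_LPS 2.

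The difference between WD and CD responses had 1067 genes at an unadjusted p under 0.05, where 528.6 are expected, and 11 of 100 shuffled groupings had at least as many, up to 1635. The count of 0 became 3 without CD_LPS 1, 6 without WD_LPS 1, 8 without WD_LPS 2 and 32 without WD_LPS 3, and 1 without CD_PBS 4. In simulated values this test recovered 37 of 100 genes changed 2-fold and 71 of 100 changed 4-fold, rates that may overstate recovery in these data.

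The LPS responses on WDtoCD and CD did not differ in any gene by the limma test. Car2 (-1.45 ± 0.40, adjusted p = 0.998, n = 4, 3, 4 and 4), Bcl3 (1.46 ± 0.42), Zbp1 (2.19 ± 0.73), Cybb (0.85 ± 0.26), Idi1 (0.65 ± 0.21) and Nlrp3 (1.26 ± 0.95) had the same adjusted p of 0.998. Interferon-stimulated (mean 0.61, adjusted p = 3.89e-07, adjusted p = 0.589 with an estimated correlation) and cholesterol biosynthesis genes (mean 0.43, adjusted p = 4.29e-07, adjusted p = 0.405 with an estimated correlation) were called higher and megakaryocyte and erythroid genes (mean -0.91, adjusted p = 1.14e-07, adjusted p = 0.406 with an estimated correlation) lower, and no single library ended these 3 calls. The other 8 of 11 called lists lost their calls without at least 1 library, and none of the 11 held with an estimated correlation. An unadjusted p under 0.05 was found for 397 genes, fewer than the 528.6 expected, and 25 of 100 shuffled groupings had at least as many. No single library changed the count of 0, and the simulated recovery was 35 of 100 genes at 2-fold and 83 of 100 at 4-fold.

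**Figure D4:**
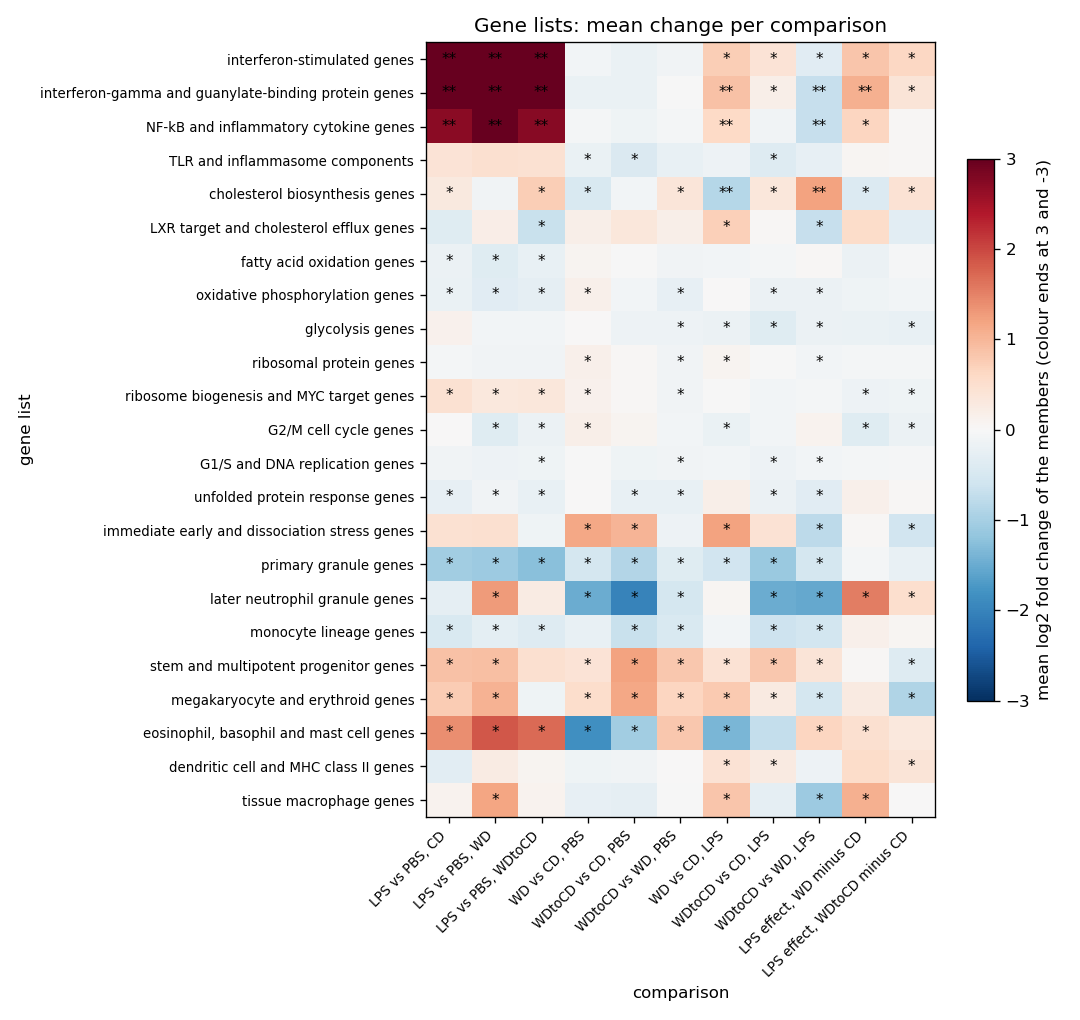
Mean log2 fold change of the members of each gene list in each comparison. A single asterisk marks a list called with the preset correlation only, and a pair of asterisks a list called with the preset and the estimated correlation.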

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

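The tests of the 3 patterns below were chosen only after the result was seen, and the divisions of libraries and list differences were planned. A library was picked out where its distance from the rest of its group exceeded Dixon's limit, in 29 of 408 groups of values tested, and chance gives about 1 in 20.

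CD_PBS 3 held low levels of genes that LPS raised, together with Xist. Over 41 genes chosen from a fit without this library, CD_PBS 3 lay above every other CD library after PBS in 30, where chance gives 6.83 and the other 5 libraries gave 0, 4, 1, 1 and 5, and its median excess was 3.93 percent of the level on CD after LPS. A response of that sample to LPS does not account for Xist, at 226 beside 36.8 at most in other libraries with Y-linked genes above Xist. Material of a library after LPS could account for both, since the Xist excess was 2.47 percent of the WD level and 2.67 percent of the WDtoCD level, inside the 10th to 90th percentile of the genes (0.393 to 3.197 and 0.418 to 6.13). For CD material it was 5.80 percent, outside that range (0.463 to 5.73) but inside the range of all genes (-3.65 to 8.78), so this source is left undecided. The first form of this test used the range of all genes and CD alone, and the narrower range and 2 more sources were added after its values were seen. Mixing in the tube and cross-talk on the sequencer cannot be told apart, since the labels name no lane or index. WD_LPS 3, 1 of 3 libraries of its group, held Xist and Y-linked genes and may be mixed too, which was not tested.

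Cholesterol biosynthesis genes were lower on WD than on CD after LPS (mean -0.86). Without the shallow library WD_LPS 3 the mean was -0.97, and with a covariate for Y-linked expression -0.85, so neither accounts for it. A supply of sterol from the diet could. The list was lower on WD after PBS too by the preset test (mean -0.45, adjusted p = 0.0538 with an estimated correlation), with 0 members called over all genes, and higher on WDtoCD than on WD after LPS (1.21). It was also higher on WDtoCD than on CD after LPS (mean 0.35, adjusted p = 0.0996 with an estimated correlation), which a supply of sterol alone does not foresee, so this stays a hypothesis.

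By the preset test, granule genes were lower and stem cell genes higher on WDtoCD than on CD after PBS (stem and multipotent progenitor mean 1.20, adjusted p = 0.0633 with an estimated correlation, and 0.0633 and 0.183 for later and primary granule genes, 2 of 15 primary members called). Fewer GMPs with more of every other cell type in the gate stays open. Eosinophil, basophil and mast cell genes lay below stem cell genes (mean -1.04, a gap of 2.24 beside 1.55, their spread over genes). Megakaryocyte and erythroid genes lay near stem cell genes (mean 1.17, adjusted p = 0.105 with an estimated correlation). Without CD_PBS 4 the gap was 1.71 beside 1.36, the narrowest of the 7 left out in turn. This cannot decide, since the fall of the eosinophil list was not established (adjusted p = 0.610 with an estimated correlation) and its call was lost without CD_PBS 4 or WDtoCD_PBS 2. Without the shallow library WDtoCD_PBS 1 the stem cell mean was 1.26, and with a covariate for Y-linked expression 1.23. A changed share of progenitor types inside the gate stays open and was not tested.

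Among divisions of the same libraries, only the real 1 of 35 reached its count for WD against CD after PBS (17 genes, highest other 2). So it was for WDtoCD against CD after PBS (1 of 35, 277 genes, 11) and LPS on CD (1 of 35, 1399 genes, 6). The same held for LPS on WD (1 of 35, 2392 genes, 1755), LPS on WDtoCD (1 of 35, 1287 genes, 545), WD against CD after LPS (1 of 35, 160 genes, 8) and WDtoCD against CD after LPS (1 of 35, 115 genes, 21). They do not exclude it for WDtoCD against WD after PBS (11 of 35 reached 1 gene, highest other 1810) and after LPS (2 of 35 reached 111 genes, highest other 396). For the differences between LPS responses, 11 of 100 regroupings reached 1067 genes at an unadjusted p under 0.05 for WD (highest 1635) and 25 of 100 reached 397 for WDtoCD (highest 1232), which does not exclude chance.

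Lists whose LPS response differed between diets by the preset test were, as mean differences, interferon-stimulated genes 0.83, interferon-gamma and guanylate-binding protein genes 1.08, NF-kB and inflammatory cytokine genes 0.65, cholesterol biosynthesis genes -0.41, ribosome biogenesis and MYC target genes -0.15, G2/M cell cycle genes -0.36, later neutrophil granule genes 1.54, eosinophil, basophil and mast cell genes 0.48 and tissue macrophage genes 1.08 for WD against CD. For WDtoCD against CD they were interferon-stimulated genes 0.61, interferon-gamma and guanylate-binding protein genes 0.39 (0.17 without CD_PBS 3), cholesterol biosynthesis 0.43, glycolysis -0.22, ribosome biogenesis and MYC target -0.12, G2/M cell cycle -0.18, immediate early and dissociation stress -0.59, later neutrophil granule 0.51, stem and multipotent progenitor -0.39, megakaryocyte and erythroid -0.91 and dendritic cell and MHC class II genes 0.39. Of these 20, only the interferon-gamma list for WD held with an estimated correlation (adjusted p = 0.0326), a difference CD_PBS 3 enlarged.

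The recovered reads of WDtoCD_LPS 4 (10.5 M) lay outside those of its group (3.52 to 4.49 M). List means, on log2 against batch 2 CD_PBS, lay outside for interferon-gamma and guanylate-binding protein genes in CD_PBS 3 (0.664), NF-kB and inflammatory cytokine genes in CD_PBS 3 (0.583) and fatty acid oxidation genes in CD_PBS 2 (0.375). The same held for fatty acid oxidation genes in CD_LPS 1 (-0.168), oxidative phosphorylation genes in CD_PBS 2 (0.562) and oxidative phosphorylation genes in CD_LPS 3 (-0.286), and for ribosomal protein genes in CD_PBS 2 (0.510) and eosinophil, basophil and mast cell genes in CD_LPS 2 (2.75). In CD_PBS 3, Saa3 (63.5), Ccl5 (92.9) and Irg1 (24.7) lay above the other CD_PBS libraries. Genes outside the rest of their group were Saa3 in WD_PBS 1 (2.09), Ccl5 in WD_PBS 3 (1.15), Iigp1 in CD_LPS 4 (777), Cracr2b in CD_PBS 2 (120.4) and Apba1 in WDtoCD_LPS 3 (7.61). Next came Cybb in CD_LPS 3 (4885), Hmgcr in WDtoCD_LPS 1 (659), Ldlr in CD_PBS 2 (699), Setd4 in CD_PBS 3 (4.70) and Setd4 in CD_LPS 1 (9.11). Further such values were Gbp6 in WD_PBS 3 (3.46), Zbp1 in WD_PBS 1 (1), Mgst1 in WDtoCD_LPS 1 (11.5), Ltb4r1 in CD_PBS 2 (385) and Fcnb in WDtoCD_LPS 4 (2.57). The last were Sqle in CD_LPS 2 (191) and Ear6 in CD_LPS 1 (65.2). Saa3 in WD_PBS 1, Ccl5 in WD_PBS 3, Gbp6 in WD_PBS 3 and Fcnb in WDtoCD_LPS 4 stood on 1, 1, 3 and 8 reads with every other library at the floor, where the rule picks out any read, so they show nothing.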

How the results depend on the processing

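Tests with row labels as deposited, without the shallow libraries, with library weights and with the Y-linked or immediate early covariate were chosen after the data were seen. Of 257 values of named genes, 202 kept direction and call with only the compared groups in the fit, 204 with library weights, 230 with the immediate early covariate, 236 without the batch covariate and at least 243 in the other settings. With labels as deposited 229 of 253 did, and with a stricter filter 110 of 113. Of 143 list calls, 141, 114, 121 (of 138) and 130 did in the first 4 of these, 131 with labels as deposited, 109 of 127 with a stricter filter, 122 without the shallow libraries, 130 with quantile normalization and at least 140 in the other settings. Leaving out each library in turn kept 1176 of 1308 list values and 1955 of 2207 gene values, a share raised by the choice of LPS list examples, and moved the mean of 58 of 143 called lists by more than 1.5 times. The planned count test was not run, since the table holds scaled values with a floor. No paired analysis was possible since the labels pair no libraries. The shallow libraries limit what low genes can show. The cause of each change below was not tested, except that fewer libraries or genes enter some fits.

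WD against CD after PBS gave 26 with quantile normalization or a pseudocount of 10 or 0.1. The overlap after PBS gave 19 with quantile normalization and 22 with a pseudocount of 10. Without the batch covariate, WD against CD after PBS gave 70, WDtoCD against CD after PBS 459, WD against CD after LPS 82 and the overlap after PBS 57. Here the overlap after LPS gave 6. With only the compared groups in the fit, WD against CD after PBS gave 34, WDtoCD against CD after PBS 511, WDtoCD against WD after PBS 0 and LPS on CD 2841. Here LPS on WD gave 895, WD against CD after LPS 48, WDtoCD against CD after LPS 50 and WDtoCD against WD after LPS 29. Without the shallow libraries, WD against CD after PBS gave 44, WD against CD after LPS 379, WDtoCD against WD after LPS 428 and the LPS response on WD against CD 30. Here the overlap after PBS gave 22 and the overlap after LPS 32. With library weights, WD against CD after PBS gave 118, WDtoCD against CD after PBS 419, WDtoCD against WD after PBS 0 and LPS on CD 4317. Here LPS on WD gave 1113, WD against CD after LPS 23, WDtoCD against CD after LPS 808 and WDtoCD against WD after LPS 17. Here the LPS response on WDtoCD against CD gave 1, the overlap after PBS 62 and the overlap after LPS 6. With the Y-linked covariate, WD against CD after PBS gave 30 and the overlap after PBS 20. With the immediate early covariate, WD against CD after PBS gave 2, WDtoCD against CD after PBS 172, the LPS response on WD against CD 2 and the overlap after PBS 2. With the lower-signal genes of a stricter filter left out, WDtoCD against CD after PBS gave 144, WDtoCD against WD after PBS 0, LPS on WD 1330 and LPS on WDtoCD 807. Here WD against CD after LPS gave 55, WDtoCD against WD after LPS 47, the overlap after LPS 10 and the overlap of the LPS responses 447. With CD libraries split between the 2 contrasts in 6 ways, the median overlap was 0 after PBS (0 to 3) and 0 each time after LPS. Leaving out each library in turn gave counts of WD against CD after PBS 2 to 26, WDtoCD against CD after PBS 106 to 278, WDtoCD against WD after PBS 0 to 2, LPS on CD 957 to 1401 and LPS on WD 1958 to 2579. For the next comparisons they were LPS on WDtoCD 740 to 1466, WD against CD after LPS 21 to 364, WDtoCD against CD after LPS 26 to 232 and WDtoCD against WD after LPS 31 to 373. The last were the LPS response on WD against CD 0 to 32, the LPS response on WDtoCD against CD 0 to 0, the overlap after PBS 2 to 17, the overlap after LPS 1 to 33 and the overlap of the LPS responses 544 to 725.

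With row labels as deposited, the sign turned for Siglecg 0.19, Socs3 -0.0260, Tifab 0.65, Tlr4 -0.18, Setd4 -0.10 and Slc40a1 0.63 (LPS on CD), Tmem119 0.84 and Zbp1 -0.0289 (LPS on WD) and Zbp1 -0.37 (LPS on WDtoCD). Here it also turned for Slc40a1 0.59 (WD against CD after PBS) and -1.38 (the LPS response on WD against CD), Tmem119 0.10 and Tnfaip3 -0.00760 (WD against CD after LPS) and Sqle -0.45 and Serpinb10 -0.16 (WDtoCD against WD after LPS). With library weights, the sign turned for Tlr4 -0.0786, Cebpa -0.0535 and Tet2 -0.0418 (LPS on CD), oxidative phosphorylation genes -0.0745 and ribosomal protein genes -0.12 (WD against CD after PBS) and ribosomal protein genes 0.10 (WDtoCD against WD after PBS). With quantile normalization, the sign turned for Cebpa -0.0451 (LPS on CD) and ribosomal protein genes 0.0130 (WDtoCD against WD after PBS) and 0.0571 (WDtoCD against WD after LPS). Without the batch covariate, the sign turned for Cebpa -0.0432 (LPS on CD) and Nlrp3 -0.14 (the LPS response on WD against CD). With the immediate early covariate, the sign turned for Cebpa -0.0580 (LPS on CD), Nlrp3 0.31, oxidative phosphorylation genes -0.0180 and ribosomal protein genes -0.0552 (WD against CD after PBS). Here it also turned for ribosomal protein genes -0.12 (WD against CD after LPS) and 0.0443 (WDtoCD against WD after LPS). With the lower-signal genes of a stricter filter left out, the mean of megakaryocyte and erythroid genes shrank from -0.53 to -0.12 (WDtoCD against WD after LPS). It kept its sign. Leaving out single libraries turned the sign of the following. For LPS on CD, Kit went from -0.0258 without CD_LPS 3 to 0.26 without CD_LPS 2. Tlr4 went from -0.0717 without CD_LPS 1 to 0.0907 without CD_LPS 4. Cebpa went from -0.0804 without CD_LPS 1 to 0.0930 without CD_LPS 3. Dnmt3a went from -0.22 without CD_LPS 1 to 0.0748 without CD_LPS 2. Tet2 went from -0.00588 without CD_LPS 1 to 0.0783 without CD_LPS 4. Nlrp3 (WD against CD after PBS) went from -1.06 without CD_PBS 4 to 0.0814 without CD_PBS 5. Nlrp3 (the LPS response on WD against CD) went from -0.40 without CD_PBS 5 to 0.74 without CD_PBS 4. Ribosomal protein genes (WD against CD after PBS) went from -0.0180 without WD_PBS 2 to 0.29 without WD_PBS 4. For WDtoCD against WD after PBS they went from -0.25 without WD_PBS 4 to 0.0578 without WD_PBS 2.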

Other observations

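Immediate early and dissociation stress genes, which cells switch on within minutes of handling, differed between libraries of the same group. Their mean, on log2 against batch 2 CD_PBS, was 2.58, 2.11, 0.21 and -0.22 in WD_PBS 1 to 4, 1.61, 1.07 and 0.35 in WDtoCD_PBS 1 to 3, 1.83, 2.44 and 0.68 in WD_LPS 1 to 3, 0.98, 1.70, 0.26 and 0.54 in WDtoCD_LPS 1 to 4 and 0.60, 0.15, 0.49 and 0.55 in CD_LPS 1 to 4. In the WD and WDtoCD groups the libraries with Y-linked genes above Xist, numbers 1 and 2, were higher than the rest. Of the same kind, CD_PBS 3 and 4 lay at 0.21 and 0.10, beside -0.21 and -0.10 in CD_PBS 5 and 6. These values were looked at after the tests.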
